A study of Mus musculus with 8 samples.

How the data were processed

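Gene expression was measured on 8 arrays, each with total RNA from mouse double positive thymocytes. The groups were taken from the sample titles: control, overnight control, Valpha2 and Vbeta5, with 2 arrays each. Each title opens with Data 1 or Data 2, and each group has 1 array under each number. Nothing in the labels says that the replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. What the arrays of a data number share across groups is not stated, so the main fit did not use the numbers as pairs. If they mark a shared experiment, the main fit leaves that pairing out.

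The authors deposited 1 table with an intensity for each of 12488 probe sets on each array. Per the labels these values are normalized; the software, the method and the scaling target are not given in the sources used here. From the values themselves, the intensity is a linear signal with 1 decimal and no value below 0. The mean after trimming 2% of the probe sets at each end lay between 250.14 and 250.16 on every array, as it would after scaling each array by a single factor. The median signal ranged from 73.65 to 110.25. Detection calls were not used here, so a low signal has no separate measure of background, and the number of arrays limits the precision.

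Control probe sets (66) were left out, which left 12422. The signal was used as deposited, with no further normalization, and log2(signal + 17) was taken, where 17 is the 20th percentile of the positive values. Between 12.24% and 24.72% of the signals on an array lay under 17. A fold change is therefore on the log2(signal + 17) scale and understates the change of dim probe sets. The dimmest 33.3% of the probe sets by mean over the arrays were left out, and 8281 were tested.

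Gene names came from the platform annotation, updated through gene identifiers with a RefSeq table of assembly GRCm38.p6, which was used for names only. Of the 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none, and no gene was named from a probe set with several. For 10817 of the 10833 the identifier was found in the RefSeq table. No coordinates are given, since no genome build applies to the signal table.

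Each of 4 comparisons was tested with limma 3.58.1 in R 4.3.3, with 1 mean per group in a single fit of the 8 arrays, eBayes with a variance trend, 4 residual and 6.328 prior degrees of freedom, and a Benjamini-Hochberg threshold of 0.05 within the comparison. All adjusted p-values below are two-sided and come from limma in this way unless another tool is named. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333 (two-sided), so none was run. Values per group are mean ± SD with n = 2, and fold changes have the standard error (SE) of the limma fit.

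A set of 27 gene lists, 19 of pathways or stages and 8 of markers of other cell types, was tested with limma's camera with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 27 lists in a comparison. Each gene was represented by its brightest tested probe set, which gave 6094 genes. Members were also counted as past the threshold over all probe sets tested and adjusted over the list alone. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in 1 direction. No list in any of the 4 comparisons passed 0.05 after adjustment when camera estimated the correlation. By fry, 7 lists passed for Vbeta5 against the overnight control, 4 for Vbeta5 against Valpha2, 2 for the overnight control against the control and 0 for Valpha2 against the overnight control.

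The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. The rule names, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold whose arrays do not overlap between the groups, or the 5 smallest p-values in each direction where fewer than 3 probe sets passed. It adds the 4 members with the smallest p and the sign of the list from each pathway list that passed, and the 14 genes of a fixed set that had a tested probe set. A fixed gene may be left out of a comparison where the number that passed is given. Of the 56 pairs of a measured fixed gene and a comparison, 12 were barred from the text because the gene did not pass and its sign turned under an alternative setting, and not all of the others are given.

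The alternatives were quantile normalization, a common median, an offset of 8.5, a floor in place of the offset, no filter on dim probe sets, leaving out the dimmest 50%, eBayes without the trend, a block for the array number, fitting only the 4 arrays compared, leaving out each array in turn, the other list tests, and the mean of a gene's probe sets. Array quality weights, which with 2 arrays per group came out the same for both arrays of a group, and leaving out the overnight control, Valpha2 and Vbeta5 arrays numbered 1 together, were added after seeing the data.

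The tests were checked on simulated data with 200 of 8281 probe sets changed, in 20 draws. For Vbeta5 against the overnight control, 18.4% of changes of 1 on the log2 scale were recovered, 74.6% of changes of 2 and 97% of changes of 3, and 6.07% of the calls were false. For Valpha2 against the overnight control the same shares were 20.4%, 80.6%, 96.9% and 5.63%. A list shifted by 0.5 on the log2 scale was found in 20 of 20 draws by camera with the preset correlation, in 15 with an estimated correlation and in 16 by fry. The simulated genes and arrays varied independently, and each probe set had the same spread on every array. In the data the estimated correlation within the shifted list, cell cycle, was 0.254. The check therefore does not cover list calls among correlated genes.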

Results

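Double positive thymocytes are immature T cells that carry both the CD4 and the CD8 coreceptor and have just assembled a T cell receptor (TCR) of an alpha and a beta chain. The series concerned engagement of this receptor with antibodies. Total RNA was measured on 8 arrays with probe sets of the Affymetrix type, 2 in each of 4 groups: a control, an overnight control, and arrays named Valpha2 and Vbeta5 after variable segments of the alpha and the beta chain. Antibody clones, doses and times are not given in the sources used here, and the labels name no time for the control or for either antibody.

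The trimmed means of the arrays lay between 250.14 and 250.16, which scaling by a single factor would fix and which does not show that the arrays were alike. The median signal ranged from 73.65 to 110.25 and the 20th percentile from 12.4 to 26.4. Across tested probe sets the 2 arrays of a group correlated at r = 0.955 for control, 0.929 for Vbeta5, 0.924 for Valpha2 and 0.867 for the overnight control, where r is across probe sets, which are not independent replicates. RNA quality differed within groups. The log2 ratio of 3' to 5' signal of the Gapdh control probe sets was 1.72 on the Valpha2 array numbered 1, 0.95 on overnight control array 1 and 0.48 on Vbeta5 array 1, against -0.28 to -0.09 on the other 5 arrays. For actin the ratios on those 3 arrays were 1.47, 0.68 and 0.39, against 0.0042 to 0.30.

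The comparison of Vbeta5 with the overnight control asks which transcripts change when the beta chain is engaged. Genes that report receptor signalling rose on the Vbeta5 arrays. Pdcd1, which encodes the inhibitory receptor PD-1, had a signal of 843 ± 411 (SD, n = 2) against 20.55 ± 10.3, a 22.0-fold rise (log2 fold change 4.46 ± 0.62 SE, limma adjusted p = 0.0143). The immediate early transcription factor Egr2 rose 9.24-fold, from 277 ± 94.5 to 2671 ± 665, and Cd5, a negative regulator of TCR signalling, rose 5.21-fold to 5047 ± 403. Cd5 was also lower in the overnight control than in the control, without passing, so part of its rise may reflect a low overnight control. The genes of the V(D)J recombinase fell: Rag1 went from 13600 ± 1570 to 2601 ± 1080 (log2 fold change -2.44 ± 0.37 SE) and Rag2 from 961 ± 316 to 77.1 ± 79.1 (log2 fold change -3.65 ± 0.54 SE).

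In all, 29 probe sets rose and 22 fell of 8281 tested (limma, Benjamini-Hochberg). They stood for 28 and 18 named genes. Besides Pdcd1 and Egr2, the largest rises were Ephx1, an epoxide hydrolase, by 3.98 on the log2 scale, Itm2a, a membrane protein that marks positively selected thymocytes, by 3.32, and Nfatc1, a calcium-dependent transcription factor, by 3.13. Basp1 (2.68), the adhesion molecule Cd2 (2.67) and Lysmd2 (2.67) followed. Besides Rag2 and Rag1, the largest falls were the corepressor Cbfa2t3 (-2.88), the cytokine signalling inhibitor Socs3 (-2.69), the transcription factor Ets2 (-2.45), Sec23a (-2.44), the clock gene Nr1d2 (-2.16) and Gtf2h4 (-2.13). The adjusted p-values of these 16 genes lay between 0.0106 and 0.0431. The naming rule required that both Vbeta5 arrays lie beyond both overnight control arrays in each gene. Sec23a and Socs3 had mean signals of 10.55 and 11.15 on the Vbeta5 arrays, and Pdcd1 a signal of 13.3 on overnight control array 1, under the offset of 17, so their fold changes depend on the offset. Rag1 had a second tested probe set that differed by only -0.06, and Sec23a, Basp1, Cbfa2t3 and Socs3 each had a second probe set of the same sign that did not pass. The 2 Socs3 probe sets were also higher in the overnight control than in the control, by 2.55 and 1.53, without passing (limma adjusted p = 0.0828 and 0.504). Part of the Socs3 fall may therefore reflect a high overnight control, although picking it as a fall against the same arrays favours a high value there.

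**Figure D1:**
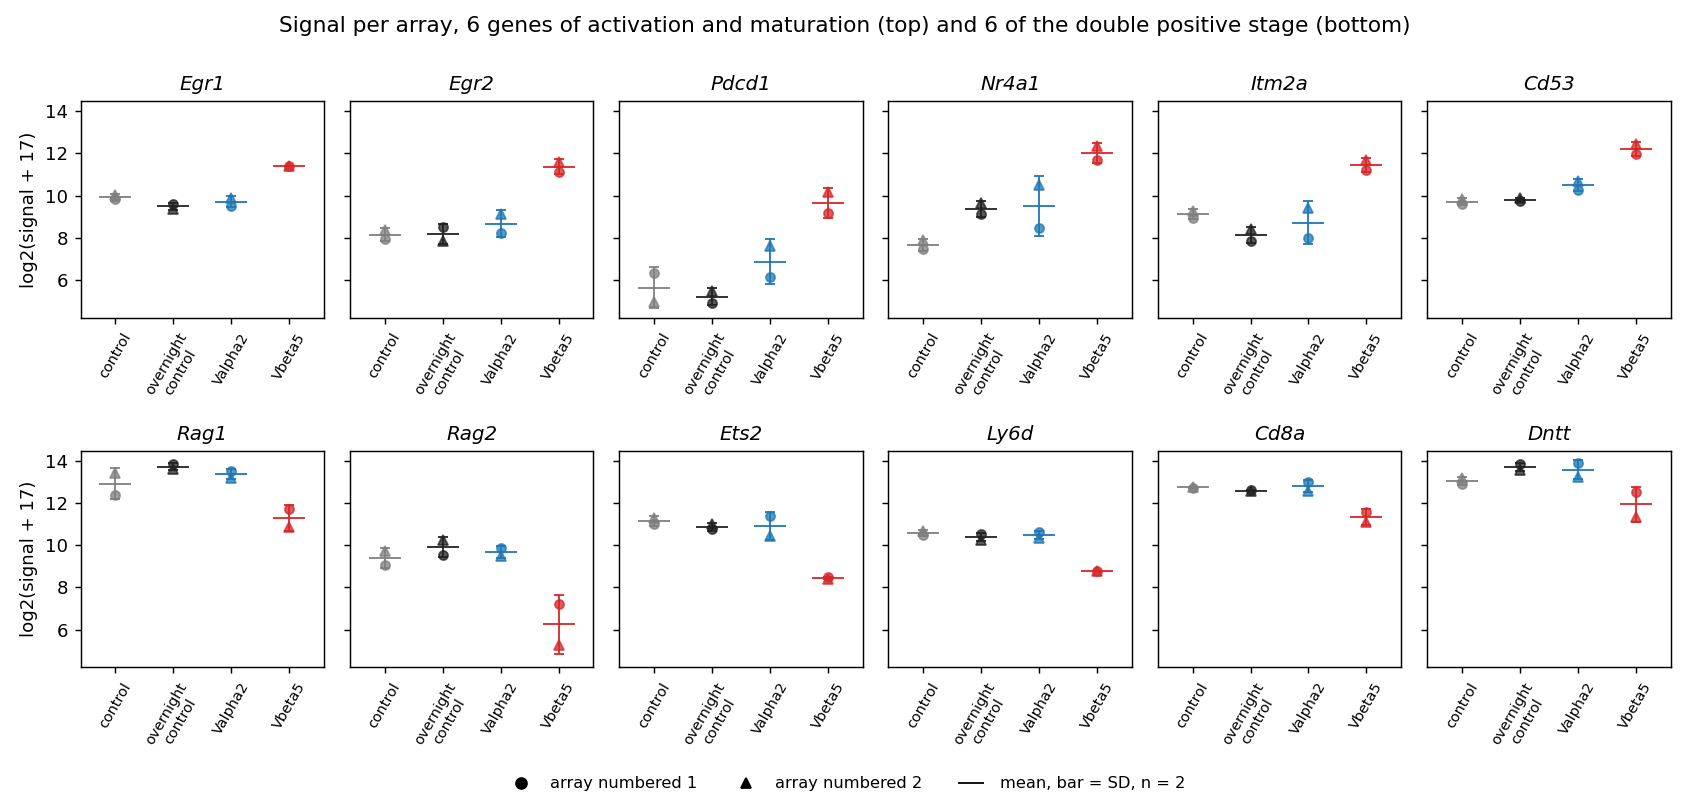
Signal of 12 genes on each array, as log2(signal + 17), with circles for arrays numbered 1, triangles for arrays numbered 2, and the mean with SD (n = 2) per group. On the Vbeta5 arrays Egr1, Egr2, Pdcd1, Itm2a and Cd53 lay above and Rag1, Rag2, Ets2 and Ly6d below the overnight control; Nr4a1, Cd8a and Dntt did not pass the test there (adjusted p = 0.0682, 0.0541 and 0.0765).

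Of the early TCR response list, 16 genes were measured; 7 rose, 0 fell and 9 did not pass, with 12 higher when adjusted over the list alone. Egr1 rose by 1.92 ± 0.22 (SE) on the log2 scale and the immediate early gene Ier2 by 1.77 ± 0.29, and the nuclear receptor Nr4a1 differed by 2.64 ± 0.53 without passing (limma adjusted p = 0.0682). The list's median was 1.65 (camera adjusted p = 2.07e-18; adjusted p = 0.105 with an estimated correlation). Of 21 measured genes of thymocyte maturation, 4 rose and 17 did not pass, with 9 higher when adjusted over the list alone. Those that rose were Itm2a, Cd2, the tetraspanin Cd53 by 2.40 ± 0.24 and the class I gene H2-K1 by 1.49 ± 0.23, although another H2-K1 probe set differed by -0.20. The median of the maturation list was 0.585 (camera adjusted p = 2.62e-09; adjusted p = 0.105 with an estimated correlation). The lineage factor Gata3 (1.10, adjusted p = 0.189), the Egr target Id3 (0.78, adjusted p = 0.244) and the survival gene Bcl2 (0.58, adjusted p = 0.671; other probe sets 1.78 and 1.21, adjusted p = 0.267 and 0.183) did not pass.

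The double positive stage list moved the other way. Of 20 measured genes 5 fell and 15 did not pass, with 12 lower and 3 higher when adjusted over the list alone, and the median was -1.15 (camera adjusted p = 9.65e-11; adjusted p = 0.105 with an estimated correlation). Rag1, Rag2, Ets2 and Ly6d (-1.63 ± 0.22 SE) were among those that fell. The coreceptor genes Cd8a (-1.26, limma adjusted p = 0.0541) and Cd4 (-1.51, adjusted p = 0.102), the terminal transferase gene Dntt (-1.78, adjusted p = 0.0765) and the pre-TCR gene Ptcra (-1.03, adjusted p = 0.566) did not pass. Of the 14 measured fixed genes, 2 rose (Cd5, Egr1) and 2 fell (Rag1, Rag2).

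Of 23 measured interferon response genes 2 rose with Vbeta5 and 21 did not pass, with 9 higher when adjusted over the list alone. The transcription factor Irf1 rose by 2.04 ± 0.38 (SE) and the guanylate-binding protein gene Gbp2 by 1.66 ± 0.26, while the immunoproteasome genes Psmb9 (1.27, adjusted p = 0.0794) and Psmb10 (1.02, adjusted p = 0.125) did not pass. The median was 0.639 (camera adjusted p = 3.61e-08; adjusted p = 0.299 with an estimated correlation). It was 1.09 without Vbeta5 array 1 and 0.380 without Vbeta5 array 2, with the list past the threshold in each case.

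Smaller shifts were found in 5 more lists. Heat shock genes had a median of 0.468 over 16 measured (0 past the threshold; 2 higher when adjusted over the list alone), with Hsph1 at 1.33 (adjusted p = 0.0596) and St13 at 1.16 (adjusted p = 0.123). Their camera adjusted p was 2.21e-05 (adjusted p = 0.105 with an estimated correlation), and their median was 0.306 without overnight control array 1. Cholesterol biosynthesis genes had a median of 0.308 over 18 measured, 0 of them past the threshold and 0 when adjusted over the list alone, with Sqle at 0.97 and Idi1 at 1.08 (camera adjusted p = 0.00423; adjusted p = 0.203 with an estimated correlation). Their median was 0.513 without overnight control array 1. Ribosome biogenesis genes had a median of 0.259 over 27 measured, 0 past the threshold and 1 when adjusted over the list alone, with Gar1 at 0.91 and Fbl at 0.82 (camera adjusted p = 0.00968; adjusted p = 0.203 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.309 over 14 measured, 0 past the threshold and 2 when adjusted over the list alone, with the clock gene Per1 at 2.21 (limma adjusted p = 0.0613). Their camera adjusted p was 0.0349 (adjusted p = 0.203 with an estimated correlation). NF-kB targets had a median of 0.239 over 15 measured, with 1 past the threshold, Irf1, and 1 when adjusted over the list alone (camera adjusted p = 0.0489; adjusted p = 0.494 with an estimated correlation). Leaving out 1 array ended 3 of these 5 calls. Without overnight control array 1 the adjusted p was 0.15 for ribosome biogenesis, 0.144 for the glucocorticoid list and 0.253 for NF-kB targets. Without Vbeta5 array 1 the latter 2 had 0.101 and 0.222, and without overnight control array 2 they had 0.0644 and 0.0535. Without Vbeta5 array 2 both calls held, with medians of 0.464 and 0.381; the NF-kB median was 0.442 without overnight control array 2. The NF-kB call also ended with a floor (adjusted p = 0.0677), without the dimmest 50% (0.0633), with no filter (0.0743) and under quantile normalization (0.0556). The glucocorticoid call ended under quantile normalization (0.0556). With the array number as a block both calls ended (camera adjusted p = 0.0804 for NF-kB targets and 0.0516 for the glucocorticoid list).

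The other 18 lists did not pass for Vbeta5 against the overnight control, with medians from -0.424 for fibroblast and endothelium markers to 0.445 for dendritic cell and MHC class II markers. The remaining pathway lists were TCR signalling machinery (median 0.147, with Nfatc1 past the threshold), pro-apoptotic (-0.085), anti-apoptotic (-0.274, with Bcl2l1 lower), cytokines and their signalling (0.059), cell cycle (-0.159), p53 targets (-0.0689), endoplasmic reticulum stress and amino acid response (0.151), glycolysis and hypoxia response (0.19), oxidative phosphorylation (0.0829), and actin cytoskeleton and adhesion (0.164, with Tpm4 and Tmsb10 higher). Marker lists of B cells (0.0296), macrophages and monocytes (0.284), granulocytes (-0.241), erythroid cells (-0.025), thymic epithelium (0.0112), and NK and gamma delta T cells (-0.0796) did not pass either.

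The total of 51 Vbeta5 calls depended on the arrays and settings used. It was 0 without Vbeta5 array 2, 26 without Vbeta5 array 1, 18 without overnight control array 1 and 31 without overnight control array 2. It was 28 after shifting each array to a common median, 28 in a fit of the 4 arrays alone, and 0 with eBayes without the trend. With the array number as a block it was 124. It was 144 without the overnight control, Valpha2 and Vbeta5 arrays numbered 1, a setting added after seeing the data.

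The comparison of Valpha2 with the overnight control asks the same of the alpha chain. No gene passed the test: of 8281 probe sets 0 rose and 0 fell by limma with Benjamini-Hochberg, the smallest adjusted p was 1, and 134 had an unadjusted p under 0.05 where 414 would be expected by chance. The count was also 0 after quantile normalization, at a common median, with either other treatment of low signals, with either other filter and without the trend. It was 1 without Valpha2 array 2, which left the Valpha2 array with the highest 3' to 5' ratio. The median standard error of a log2 fold change was 0.379, and 80.6% of simulated changes of 2 were recovered at this size. The simulation gave all arrays the same independent spread, which these data did not have. The log2 difference between the 2 overnight control arrays had an SD of 0.848, against 0.514 for control. Same-numbered overnight control and Valpha2 arrays also deviated together (r = 0.345), which the main fit does not take into account. With the array number as a block the count was still 0. The share of true changes that this comparison could recover is therefore not known.

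The smallest p-values with Valpha2 belonged to Retreg1, at 0.86 ± 0.24 (SE), Vax2, Cpt1a, a mitochondrial fatty acid import enzyme, at 0.73 ± 0.22, Cd59a and Ndufb2 among the higher genes. Among the lower they belonged to Cyp2c38, Krtdap, Rps13, Cnot4 and Lsr; all 10 had an adjusted p of 1. Rag1 differed by -0.37 ± 0.37 (SE), from 13600 ± 1570 to 10590 ± 1690 (SD, n = 2), and Egr1 by 0.22 ± 0.22, both with an adjusted p of 1. Cd4 differed by -0.40 ± 0.35 and Bcl2l11, a pro-apoptotic gene, by 0.42 ± 0.27 with other probe sets at -0.20 and -0.96, and 0 of the 14 measured fixed genes passed.

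Of the 27 lists 2 passed for Valpha2 by camera. Interferon response genes had a median of 0.224 over 23 measured, with 0 past the threshold and 0 when adjusted over the list alone (camera adjusted p = 0.00716; adjusted p = 0.805 with an estimated correlation). Irf9 differed by 0.80, Isg15 by 1.33, Gbp2 by 0.51 and Usp18 by 1.42, each with an adjusted p of 1. The interferon median was 0.0106 without Valpha2 array 2 (adjusted p = 0.439), 0.113 without overnight control array 2 (adjusted p = 0.478) and 0.355 without overnight control array 1. Oxidative phosphorylation genes had a median of 0.168 over 31 measured, again with 0 past the threshold and 0 when adjusted over the list alone (camera adjusted p = 0.00716; adjusted p = 0.805 with an estimated correlation); Ndufb5 differed by 0.39, Ndufa5 by 0.48, Atp5j by 0.39 and Uqcrq by 0.38. Their median was 0.0801 without Valpha2 array 1 (adjusted p = 0.461), 0.110 without overnight control array 1 (adjusted p = 0.377), and -0.0238 without the 3 arrays of lower RNA quality. Both calls also ended under quantile normalization (adjusted p = 0.0902 for interferon and 0.228 for oxidative phosphorylation). The medians there were 0.195 for interferon and 0.0754 for oxidative phosphorylation. Early TCR response genes had a median of 0.206 (camera adjusted p = 0.114), thymocyte maturation genes 0.0755 (0.367 by camera) and double positive stage genes -0.0927 (0.848 by camera).

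The direct comparison of Vbeta5 with Valpha2 tests the difference between the 2 antibodies without the overnight control. Since clones and doses are not given, an effect of the chain cannot be told apart from one of antibody or dose. Activation and maturation genes were higher with Vbeta5: Egr2 by 2.71 ± 0.36 (SE) on the log2 scale, at 2671 ± 665 against 408 ± 181 (SD, n = 2), Egr1 by 1.71 ± 0.22, Itm2a by 2.74 ± 0.42, Cd2 by 2.40 ± 0.38 and Cd53 by 1.70 ± 0.24. Genes of the double positive stage were lower: Rag2 by -3.44 ± 0.54, at 77.1 ± 79.1 against 812 ± 169, Ets2 by -2.47 ± 0.30, Ly6d by -1.72 ± 0.22 and Cd8a by -1.47 ± 0.24. Rag1 differed by -2.07 ± 0.37 with a limma adjusted p of 0.0547.

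In this test 8 probe sets rose and 15 fell (limma, Benjamini-Hochberg), standing for 8 and 13 named genes. The other rises were Basp1 (2.36), Crybg1 (1.74) and Dipk2a (1.53). The other large falls were Cbfa2t3 (-2.72), Sec23a (-2.48), Gtf2h4 (-1.87), Bcl2l1 (-1.63), which encodes the survival factor Bcl-xL, and Wdr78 (-1.63). Their adjusted p-values, with those of the genes above that passed, lay between 0.0284 and 0.0454. Of the 23 calls, 21 were also called in the same direction for Vbeta5 against the overnight control; the Vbeta5 arrays and the estimate of spread are common to both tests, so the overlap is no independent count. Of the 14 measured fixed genes 1 was higher (Egr1) and 2 were lower (Rag2, Cd8a). Nr4a1 (2.51, adjusted p = 0.102), Cd5 (1.84, adjusted p = 0.126), Dntt (-1.64, adjusted p = 0.131) and Gata3 (1.07, adjusted p = 0.244) did not pass.

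Early TCR response genes had a median difference of 1.56 between the antibodies, with 2 of 16 higher and 11 when adjusted over the list alone (camera adjusted p = 9.59e-16; adjusted p = 0.179 with an estimated correlation). Besides Egr1 and Egr2, Nab2 differed by 2.14 and the phosphatase gene Dusp2 by 1.46 without passing. For thymocyte maturation the median was 0.714, with 3 of 21 higher and 10 when adjusted over the list alone (camera adjusted p = 4.99e-08; adjusted p = 0.179 with an estimated correlation). For the double positive stage it was -1.11, with 4 of 20 lower and 11 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.33e-10; adjusted p = 0.179 with an estimated correlation). These 3 lists passed without each array in turn.

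A further 4 lists passed between the antibodies, with 0 members past the threshold in each. Cholesterol biosynthesis had a median of 0.448, with 2 higher and 1 lower of 18 when adjusted over the list alone; Idi1 differed by 1.36 and Cyp51 by 1.61 (camera adjusted p = 0.00129; adjusted p = 0.205 with an estimated correlation). Interferon response had a median of 0.424, with 4 of 23 higher when adjusted over the list alone and Irf1 at 1.86 (camera adjusted p = 0.000702; adjusted p = 0.504 with an estimated correlation). That median was 0.0808 without Vbeta5 array 2 (adjusted p = 0.544) and 0.688 without Vbeta5 array 1. Heat shock had a median of 0.338, with 1 of 16 higher when adjusted over the list alone and Hsph1 at 1.16 (camera adjusted p = 0.00571; adjusted p = 0.198 with an estimated correlation). It did not pass without Valpha2 array 1 (median 0.175, adjusted p = 0.0998) or Vbeta5 array 2 (adjusted p = 0.183). Dendritic cell and MHC class II markers had a median of 0.591 over 11 measured, 0 of them higher when adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.579 with an estimated correlation). This call ended without Valpha2 array 2 (adjusted p = 0.141), Vbeta5 array 1 (0.0627) or Vbeta5 array 2 (0.0879, median 0.335), and with the mean of a gene's probe sets (0.0869).

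The 23 calls between the antibodies became 0 without Valpha2 array 1, Vbeta5 array 2, or either control array, which enter only through the shared estimate of spread. They were also 0 at a common median, in a fit of the 4 arrays alone, and without the trend, but 90 with the array number as a block.

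**Figure D2:**
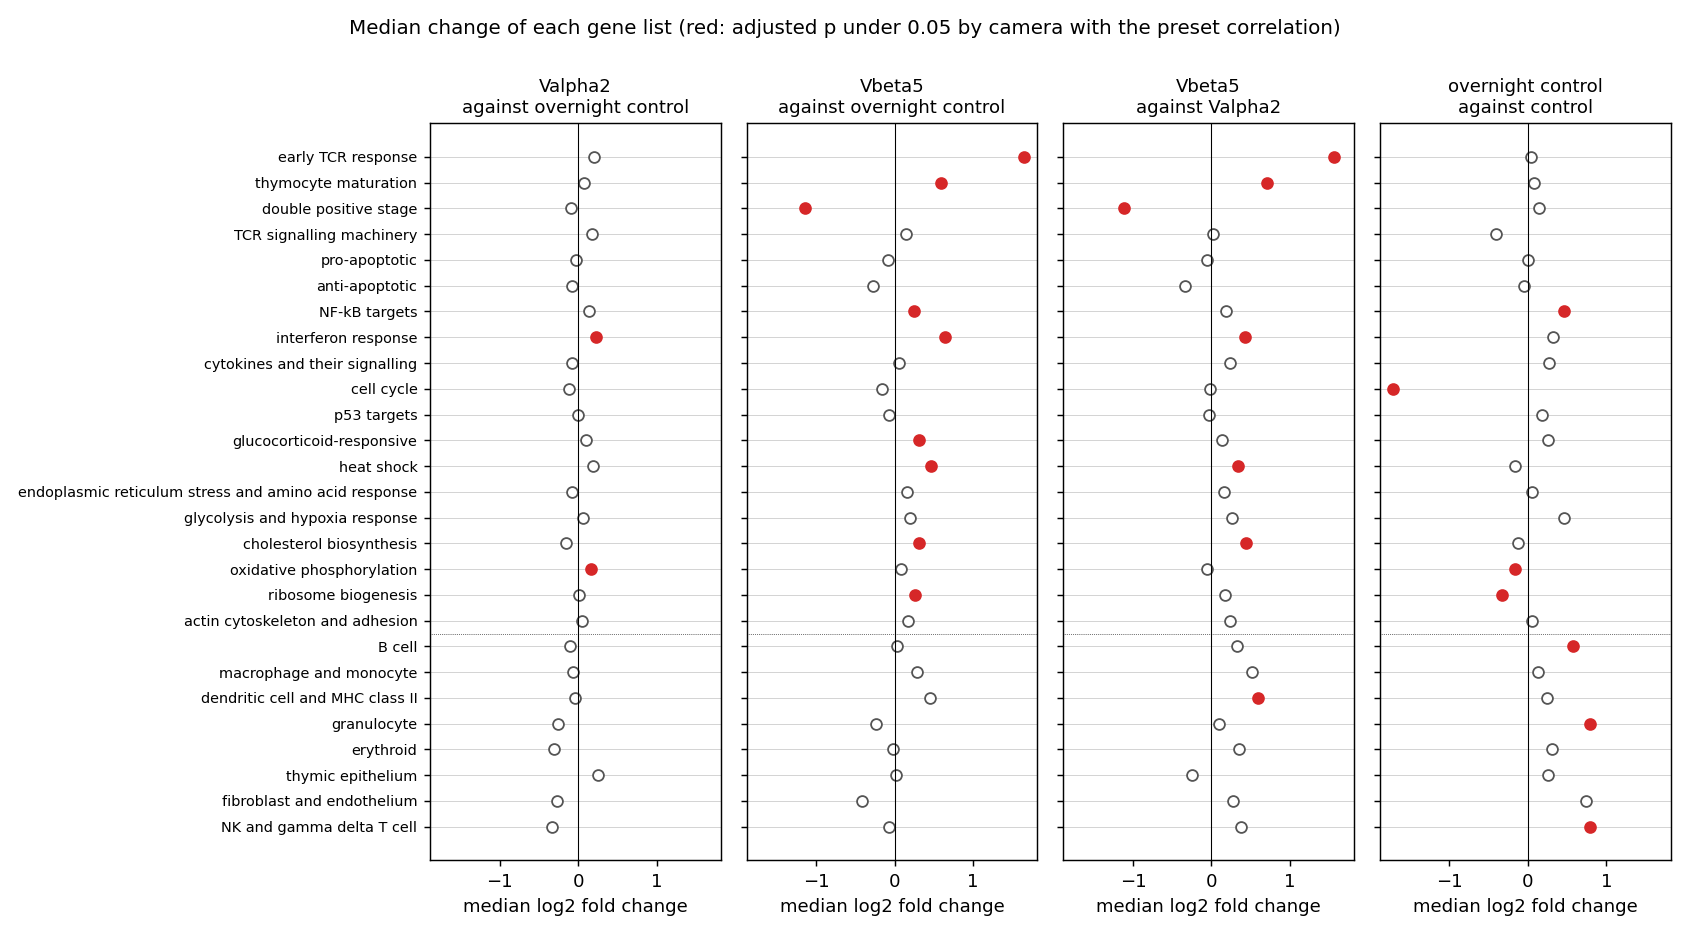
Median log2 fold change of each of the 27 gene lists (x axis) in the 4 comparisons, with red points where camera with the preset correlation gave an adjusted p under 0.05; the dotted line parts the 19 pathway lists from the 8 marker lists. With Vbeta5 the early TCR response median was 1.65 and the double positive stage median -1.15, against 0.206 and -0.0927 with Valpha2, and the cell cycle median was -1.72 in the overnight control.

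Across the 8281 probe sets, the log2 fold changes with Valpha2 and with Vbeta5 against the same overnight control arrays correlated at r = 0.387, with a covariance of 0.0783. The correlation is across probe sets, which are not independent replicates. Unchanged groups simulated against those shared controls gave r = 0.501 (0.477 to 0.532 in 100 draws) and a covariance of 0.0924, and the spread of the 2 overnight control arrays themselves gave an expected covariance of 0.184. The observed values lay below these, but the simulation treats arrays of different groups as independent, while same-numbered arrays deviated together (r = 0.104 to 0.345 over the 6 pairs of groups). With 2 control arrays the controls could not be split into pairs. Taken array by array with no array in common, r was 0.025 for Vbeta5 array 1 with Valpha2 array 2 and -0.182 for the reverse. The value was 0.6045 without overnight control array 1, 0.717 without overnight control array 2 and 0.211 without Valpha2 array 2. No gene passed the threshold with both antibodies, since none passed with Valpha2. Among probe sets called with Vbeta5, the 29 that rose had a median change of 2.04 with Vbeta5 and 0.334 with Valpha2, and the 22 that fell had -1.88 and -0.113. These probe sets were picked for their Vbeta5 change, which by itself favours a larger median with Vbeta5. The Valpha2 medians differed between the array numbers: 0.14 on number 1 and 0.717 on number 2 for those that rose, and 0.151 and -0.421, with opposite signs, for those that fell. At these probe sets the overnight control itself differed from the control by medians of -0.43 and 0.347. Such opposite signs are favoured by the picking, which used the same overnight control arrays.

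**Figure D3:**
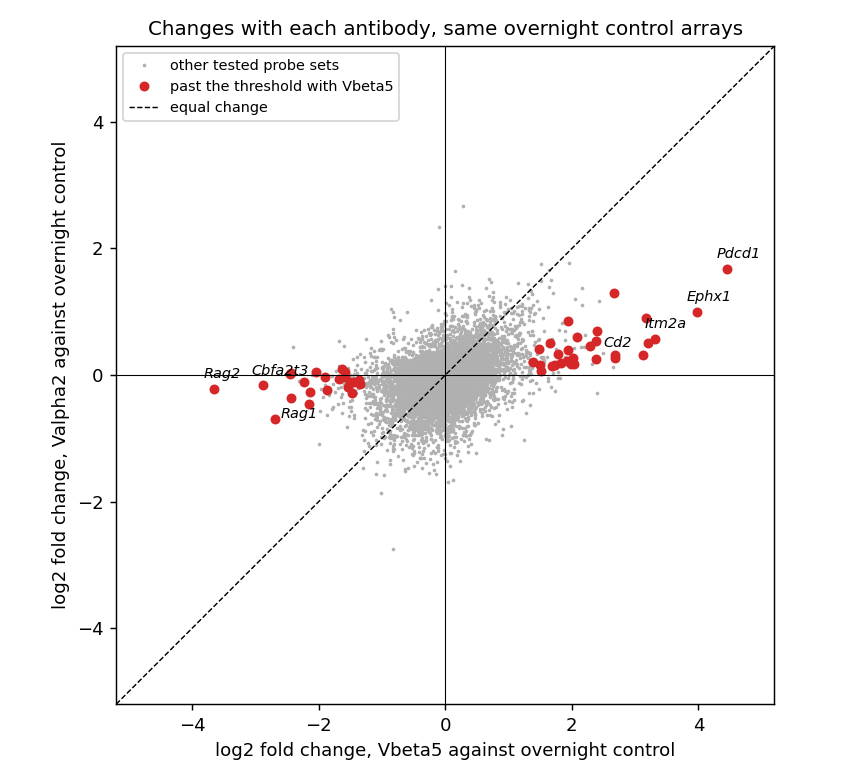
Log2 fold change of each of the 8281 tested probe sets against the overnight control, with Vbeta5 (x axis) and with Valpha2 (y axis), red where the Vbeta5 change passed the threshold and with a dashed line of equal change. The 51 red points have medians of 0.334 with Valpha2 and 2.04 with Vbeta5 for those that rose. They were picked for their Vbeta5 change, which by itself favours larger values on the Vbeta5 axis.

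The comparison of the overnight control with the control shows what differed between the arrays without antibody. Several genes that act in DNA replication, members of the cell cycle list among them, were lower in the overnight control. Rrm2, a subunit of ribonucleotide reductase, fell from 1928 ± 295 to 180 ± 132 (SD, n = 2), a log2 fold change of -3.475 ± 0.46 (SE), and Rrm1, its partner, had -2.43 ± 0.37. The replicative helicase genes Mcm5 (-2.14 ± 0.24) and Mcm3 (-1.85 ± 0.28) and the origin licensing factor Cdc6 (-2.49 ± 0.35) fell as well. Timp1, an inhibitor of metalloproteinases, was the single gene that rose, by 2.51 ± 0.37, from 83.0 ± 36.8 to 549 ± 181.

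In all, 1 probe set rose and 14 fell (limma, Benjamini-Hochberg), and 745 had an unadjusted p under 0.05 where 414 would be expected by chance. Other large falls were Tcf19 (-3.36), the PCNA-binding factor Pclaf (-2.94), Uhrf1 (-2.84), which maintains DNA methylation, and the histone chaperone Asf1b (-2.41). The adjusted p-values of the 9 genes with the largest changes lay between 0.0211 and 0.0333. A second, dimmer Mcm5 probe set differed by 0.90 and did not pass. The median of all tested probe sets was 0.0991 in this comparison, -0.127 at a common median and 0.0188 after quantile normalization; the changes of the falling genes named above, -3.475 to -1.85, were larger in size.

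Of the 34 measured cell cycle genes 6 fell and 28 did not pass, with 32 lower when adjusted over the list alone and a value below 0 for all 34. The median was -1.72 (camera adjusted p = 7.13e-47; adjusted p = 0.138 with an estimated correlation). It ranged from -1.78 to -1.52 without each array in turn and the list passed each time. The antibody arrays were as low: the median difference from the mean of the controls was -1.75 and -1.52 on the overnight control arrays 1 and 2, -1.75 and -1.73 with Valpha2, and -1.84 and -1.42 with Vbeta5.

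**Figure D4:**
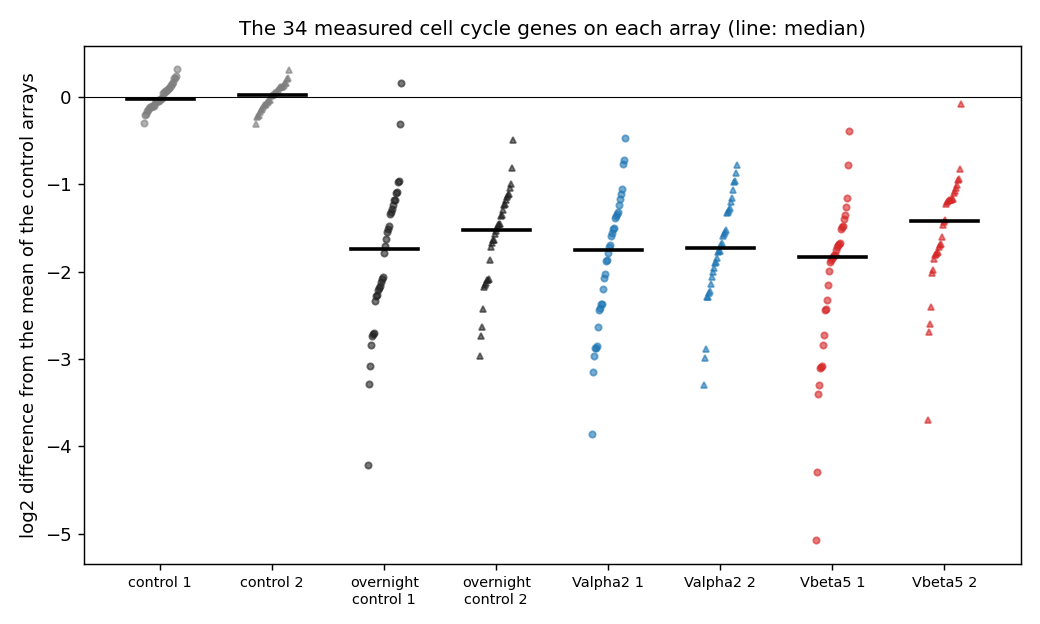
Difference of each of the 34 measured cell cycle genes from its mean over the control arrays (y axis, log2 units) on each of the 8 arrays (x axis), with a line at the median. The 6 arrays other than the controls have medians between -1.84 and -1.42.

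Ribosome biogenesis genes had a median of -0.334, with 0 of 27 past the threshold and 3 lower when adjusted over the list alone; Ran differed by -0.99 and Ranbp1 by -0.99 (camera adjusted p = 0.00308; adjusted p = 0.338 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.166, with 0 of 31 past the threshold and 0 when adjusted over the list alone; Uqcrq differed by -0.58 (camera adjusted p = 0.0435; adjusted p = 0.676 with an estimated correlation). NF-kB targets had a median of 0.464, with 0 of 15 past the threshold and 1 higher when adjusted over the list alone, Gadd45b at 1.64 (camera adjusted p = 0.0442; adjusted p = 0.671 with an estimated correlation). The oxidative phosphorylation call ended without overnight control array 1 (median -0.0736, adjusted p = 0.391) or control array 2 (adjusted p = 0.129). The NF-kB call ended without control array 2 (adjusted p = 0.273), overnight control array 2 (median 0.157, adjusted p = 0.352), Valpha2 array 1 (0.0667) or Valpha2 array 2 (0.0698). The NF-kB call also ended with a floor (adjusted p = 0.0663), without the dimmest 50% (0.051), with no filter (0.182) and in a fit of the 4 arrays (0.0741). It ended too with the mean of a gene's probe sets (0.0545), under quantile normalization (0.135) and with the array number as a block (camera adjusted p = 0.0629). The oxidative phosphorylation call ended without the dimmest 50% (0.106), in a fit of the 4 arrays (0.051), with the mean of probe sets (0.104) and under quantile normalization (0.369).

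Marker lists of B cells (median 0.569), granulocytes (0.792), and NK and gamma delta T cells (0.796) were higher in the overnight control, each with 0 members past the threshold (camera adjusted p = 0.0435 each). With an estimated correlation the adjusted p-values were 0.636, 0.671 and 0.636, and adjusted over the list alone 0, 0 and 1 members were higher. Overnight control array 1 had a raised low end, with 12.24% of signals under 17 against 24.17% on array 2. Without it the medians were 0.0207, 0.225 and 0.426 and the adjusted p-values 0.391, 0.432 and 0.301; without overnight control array 2 the medians were 1.07, 1.30 and 1.47. The B cell and NK calls also ended without control array 2 (adjusted p = 0.0685 and 0.0738), and the granulocyte call without control array 1 (0.0925). Under quantile normalization all 3 calls ended (adjusted p = 0.0513 for B cells, 0.0513 for granulocytes and 0.0643 for NK and gamma delta T cells). The medians there were smaller but stayed above 0, at 0.3905, 0.6467 and 0.6216. Other marker lists leaned the same way without passing: fibroblast and endothelium (median 0.744, 6 of 7 above 0), erythroid (0.309, 6 of 7), thymic epithelium (0.254, 5 of 5), and dendritic cell and MHC class II (0.25, 9 of 11). Macrophage and monocyte markers did not (0.13, 4 of 8). The 3 calls also ended with no filter on dim probe sets (adjusted p = 0.0705 for B cells, 0.0668 for granulocytes and 0.0876 for NK and gamma delta T cells) and in a fit of the 4 arrays alone (0.051 each).

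None of the 14 measured fixed genes passed between the overnight control and the control. Nr4a1 differed by 1.70 ± 0.53 (SE, limma adjusted p = 0.333), Cd5 by -1.50 ± 0.41 (adjusted p = 0.234) and Rag1 by 0.81 ± 0.37 (adjusted p = 0.558). The 15 calls were 0 without control array 1, control array 2 or overnight control array 1, and 119 without overnight control array 2. They were 31 in a fit of the 4 arrays alone, 99 with the array number as a block and 0 without the trend.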

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

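Array quality weights, and leaving out the overnight control, Valpha2 and Vbeta5 arrays numbered 1 together, were chosen only after the results were seen. In the order Vbeta5 against the overnight control (51 calls), Vbeta5 against Valpha2 (23) and the overnight control against the control (15), the counts were 14, 50 and 7 with array quality weights (the same for both arrays of a group, so that they do not lower a single array), 28, 0 and 31 in a fit of the 4 arrays compared, and 144, 41 and 69 without the arrays numbered 1 of those 3 groups. All 3 counts were 0 with eBayes without the trend. At a common median the first was 28 and the second 0. Leaving out each array in turn gave 0 to 54, 0 to 31 and 0 to 119 calls, and 0 to 1 for Valpha2 against the overnight control. A group left with 1 array was assumed to vary like the others. Counts stayed within 1.5 times of those reported under quantile normalization, an offset of 8.5, a floor, no filter and a stricter filter. Genes named by the fixed rule made up 51 calls over all comparisons, which are not the 51 Vbeta5 calls. None of these changed direction in a setting run, but all 51 lost the call without the trend. The rule named the largest changes only where arrays did not overlap, so leaving out an array could not turn their sign. The correlation of the antibody responses ranged from 0.2108 to 0.7172 without each array in turn.

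The titles share the names Data 1 and Data 2 between groups. The deviations of same-numbered arrays from their group means correlated between 0.104 and 0.345 over the 6 pairs of groups, across probe sets. With 2 numbers and no label that says what a data number shares, the main fit did not treat same-numbered arrays as pairs. With the number as a replicate block the counts were 124, 90 and 99, and 0 for Valpha2. All 51, 23 and 15 calls were among these. Of the called lists, the block ended 3 (NF-kB targets in both comparisons and the glucocorticoid list) and changed no other.

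Of the 25 list calls, 16 held under quantile normalization, 12 by fry and 0 by camera with an estimated correlation. Quantile normalization ended both Valpha2 calls, the glucocorticoid and NF-kB calls with Vbeta5, and, for the overnight control against the control, those of B cells, granulocytes, NK and gamma delta T cells, NF-kB targets and oxidative phosphorylation. The oxidative phosphorylation list with Valpha2 reversed to -0.02377 without the 3 arrays numbered 1; the cause was not tested. Why the other counts moved was not tested either. Leaving out arrays also lowers their number, but counts both rose and fell in those settings. The low signals limit dim genes, since no measure of background was used.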

Other observations

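The tests of the Valpha2 response and of the cell cycle genes were chosen only after the results were seen, and the genes of the next paragraph were chosen after their values were seen.

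Besides the recombinase genes, Vbeta5 lowered Xrcc6, which encodes the Ku70 subunit of the end-joining machinery that seals V(D)J breaks, by -1.58 ± 0.27 (SE) on the log2 scale (limma adjusted p = 0.0301), and against Valpha2 by -1.62 (adjusted p = 0.0447). Bcl2l1 fell by -1.87 ± 0.26 (adjusted p = 0.0143) and was the single member of the 14 measured anti-apoptotic genes past the threshold. Of the 11 measured pro-apoptotic genes 0 passed, with a median of -0.085 (camera adjusted p = 0.741). Of the 26 measured genes of the actin list 2 rose against the overnight control, Tpm4 by 2.29 and Tmsb10 by 1.94, and outside the list the actin-binding protein genes Lcp1 and Cnn2 rose by 2.08 and 1.74, with adjusted p-values from 0.0116 to 0.0211; a second Lcp1 probe set differed by 0.87 and did not pass. Against Valpha2 none of the 4 passed, with adjusted p = 0.0526 for Tpm4, Lcp1 and Cnn2. The actin list as a whole did not pass (median 0.164, camera adjusted p = 0.172), and Anxa2, a member, differed by -1.40.

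All 29 probe sets that rose with Vbeta5 had a log2 fold change above 0 with Valpha2, and 17 of the 22 that fell had one below 0, but the direction rested on the arrays numbered 2 (medians 0.717 and -0.421), with 0.14 and 0.151 on those numbered 1. A Valpha2 response as large as that to Vbeta5, hidden by degraded RNA on Valpha2 array 1, was tested on 100 probe sets picked on the arrays numbered 1. Their median Valpha2 change on the arrays numbered 2 was 0.31 of the Vbeta5 change (95% bootstrap interval over probe sets -0.0469 to 0.616). The interval did not reach 1, the value predicted for such a response. The test was weak, since in this direction the picked probe sets hardly carried over for Vbeta5 itself. On the arrays numbered 2 their signed Vbeta5 median was 0.491, with 62 of 100 above 0, against 59 with Valpha2. For probe sets picked on the arrays numbered 2, the Vbeta5 median on those numbered 1 was 0.989. There 86 of 100 were above 0, against 39 with Valpha2. That direction reads the degraded Valpha2 array, so it cannot test this explanation. An equally large response was therefore not excluded by the test on the arrays numbered 2. In a fit without Valpha2 array 1, Vbeta5 still differed from Valpha2 by a median of 1.125 for early TCR response genes. The medians there were 0.5202 for thymocyte maturation and -1.076 for the double positive stage. Equal responses would put these medians near 0, but the Valpha2 side then rests on 1 array, which does not settle the question. The shared control arrays may account for the common direction on the arrays numbered 2. Over the 100 probe sets picked on the arrays numbered 1, the signed Valpha2 median on the arrays numbered 2 was 0.152. Its interval (-0.0101 to 0.229) includes 0. With the numbers exchanged the median was -0.236 (-0.38 to -0.0431), which goes against a shared response on the arrays numbered 1, where the Valpha2 and the overnight control array both had raised 3' to 5' ratios of Gapdh (1.72 and 0.95), and leaves the part of the shared control there undecided. A weaker response to Valpha2 remains a hypothesis that the interval up to 0.229 leaves room for, and probe sets are not independent, so these intervals are too narrow.

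Cell cycle genes were lower in the overnight control than in the control by a median of -1.72. Degraded RNA on overnight control array 1 was argued against by the arrays numbered 2, where the median was -1.55 (-1.78 between the arrays numbered 1) and 34 of 34 genes were lower. Scaling was argued against by quantile normalization, after which the median was -1.69 (95% bootstrap interval -1.93 to -1.37). The medians of Valpha2 and Vbeta5 against the control were -1.72 and -1.68, with 34 of 34 genes lower in each, which is consistent with an effect of culture shared by all arrays other than the controls, antibody or not. This is a hypothesis: the labels name no time for the antibody arrays, and a separate preparation of the controls stays open and was not tested.

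Markers of B cells, granulocytes, and NK and gamma delta T cells were higher in the overnight control, a pattern whose tests were written before their values were seen. Between the arrays numbered 1 the median over 19 markers was 1.29, and between the arrays numbered 2 it was 0.114 (95% bootstrap interval -0.205 to 0.427), which leaves the raised low end of overnight control array 1 open as a source. More cells of these types remain open: all 3 of the brightest markers were higher between the arrays numbered 2, but Ighm by 0.086 and Csf3r by 0.114 only, with Gzma at 1.09. Between the arrays numbered 1 Ighm, the brightest of the 3, differed by -0.00067, but Csf3r and Gzma, at a mean log2 of 8.556 and 8.773, by 1.64 and 1.6, so the low end alone may not be the whole source. Ighm had a mean log2 of 11.82, while the other B cell markers lay between 6.429 (Blk) and 7.913 (Cd79b). Whether the Ighm signal came from B cells is therefore not known, and its small differences do not weigh on either source. The source label names double positive thymocytes, no sort is described in the sources used here, and 1 of the 19 markers, Cd74, is also in the dendritic cell list.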
